A study of Arabidopsis thaliana with 4 samples.

How the data were processed

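Root tips of Arabidopsis thaliana (Col-0) were profiled on 4 Agilent 2-colour gene expression arrays, all on 1 slide and from 1 scan, so slide and scan date gave no batches to compare. Per the labels' protocols, seedlings were grown on nutrient agar at 23 °C under 16 h of light and 8 h of darkness until 2 days after germination, and total RNA came from root tips of about 1 cm. On 2 arrays the smb brn1 brn2 triple mutant was hybridised against wild type, and on 2 arrays SMB-overexpressing roots were hybridised against control roots after 17 h on medium with the inducer dexamethasone. What the control roots of the overexpression comparison were, beyond that name, is not given in the sources used here. The labels state that the replicates of each comparison were dye-swapped and came from independently isolated RNA pools, so each array was 1 replicate (n = 2 per comparison). Whether the pools came from plants grown apart is not given in the sources used here. The p-values therefore measure only the spread between these arrays, which differ in pool and in dye orientation, and that spread may be technical.

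Spot signals were deposited by the authors as linear intensity values (mean and local background brightness of Cy3 and Cy5), extracted with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. Processed signals were deposited as intensity values as well; per the file headers they were background-subtracted, spatially and multiplicatively detrended and dye-normalised within each array, with surrogate values for dim spots. Log ratios were deposited as log10 of red (Cy5) over green (Cy3) processed signal, per the file headers. The deposited value table of the series, keyed by spot number, held the same log10 ratios, with a largest difference of 5e-10 from those in the scanner files and a median of 0 in each column. Its scale, direction and centring were therefore known from the scanner files. Median spot brightness was 263 to 318 in Cy3 and 395 to 473 in Cy5, against median local backgrounds of 35 to 37 and 53.5 to 63. Between 69.1% and 77.6% of the gene spots were well above background in a channel, no spot was saturated (0 on each array), and 16 to 21 spots per array carried an outlier flag. The number of arrays limits the precision of the ratios.

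Each array's ratio was turned to triple mutant over wild type or overexpression over control from the dyes that the labels give to each channel. Background was corrected with normexp (offset 50) on the mean signals with the local background medians, and log2 ratios were normalised within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 (with statmod 1.5.0 and version 1.17.8 of data.table). Control spots and spots with an outlier flag were then left out and the spots of a probe averaged. Each array held 45220 spots, of which 1417 were controls and 43803 belonged to 43603 gene probes. A reference table of the TAIR10.1 assembly gave a locus for 36669 of these probes: 34285 by RefSeq accession, 1852 by a locus tag in the array's name or description and 532 by a symbol of a single gene. The accession and the gene name gave different loci for 17 probes, and the accession was used. The 6934 probes without a locus were kept out of the comparisons and tested separately. The probe coordinates in the array files refer to an older build than the table, so the table served only for names and for which genes neighbour each other, and no coordinates are given.

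Probes were kept when well above background on both arrays of at least 1 of the 4 RNA groups, and each gene was represented by its brightest probe, which left 20938 genes. Where the probes of a gene disagree, the brightest one decides the value. Among the genes reported by name, the second probe of ADS4 read 1.34 in the mutant, that of AT2G37870 read 0.59 and that of FAR1 read 0.17. Other probes read 2.37 and 0.24 for AT4G23680, 1.34 and 0.49 for SEN1 and 1.60 and 0.43 for EXPA8 in the mutant. On overexpression the second probe of PCK2 read -0.18 and that of XTH4 read 0.36, and the other probes of EXPA8 read -0.68 and -0.16. Genes were tested with limma (lmFit and eBayes) on all 4 arrays together, which shared an estimate of the spread, and were called at a Benjamini-Hochberg adjusted p under 0.05. A gene whose probe was not well above background on either array of a group has only a bound there. Its fold is given as at least the bright group's mean over the dim group's mean, with the lowest signal well above background as a floor, from single-channel values after loess and between-array (Aquantile) normalisation.

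The genes named in the text were set by a rule: SMB, BRN1, BRN2 and RCPG; the 10 highest and 10 lowest genes of each comparison among those called with the same sign on both arrays; up to 4 members with the smallest p in each gene list; and the 10 genes called in both comparisons with opposite signs, and with the same sign, whose smaller change was largest. Of the genes this rule names, 1 is not reported here. The rule, the 19 gene lists (286 members, without the targeted genes), the tests and the alternatives were fixed before the data were examined. The lists covered developmental programmed cell death, cell separation enzymes, other NAC regulators, the secondary cell wall, lignin biosynthesis, expansins and xyloglucan enzymes, root hair cells, epidermal patterning, columella with starch and gravity sensing, the root stem cell niche and meristem, the mitotic cell cycle, DNA replication, the endodermis and Casparian strip, suberin and cutin, phloem, photosynthesis as a marker of shoot tissue, defence and jasmonate, auxin response, and ER bodies. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with camera at an estimated correlation and with fry. Camera with an estimated correlation rests on the 2 residual degrees of freedom of the fit, which leave it little power. A list call lost with it therefore cannot be put down to correlation between the genes. Members were also counted with p adjusted over the list alone. In addition, 32 gene families of at least 5 genes were formed by whole-word keywords in the array's descriptions and the reference names, and tested in the same way. Overlaps of calls were tested with Fisher's exact test, two-sided. A list of 28 rapid stress and touch response genes was written after the data had been seen.

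The alternatives were no background correction, normexp with offset 0, the processed signals, median centring in place of loess, between-array normalisation, no filter and a filter on all 8 channels, saturated probes left out, the mean of all probes of a gene, the replicate number (which is also the dye orientation) as a block, each comparison fitted alone, separate channels, a trended robust prior, a log2 ratio of at least 1, each array left out in turn, the deposited value table, and both other set tests. Chosen after the data had been seen were all probes without regard to a locus, a crossed pairing of the arrays, and families without the rapid stress and touch response genes. Groups of 2 arrays allow no count of other splits of the samples. The fit was tested on simulated data with changes set in 67 genes at a log2 size of 0.5, 67 at 1 and 66 at 2 among 20938. In the mutant comparison 1.49%, 47.8% and 98.5% of them were recovered, and 7.55% of the calls were false. In the overexpression comparison none of the 67 genes at 0.5 was called (0%), 52.2% and 98.5% were recovered at 1 and 2, and 3.85% of the calls were false. Noise in the simulation was drawn independently for each gene, without effects shared by the genes of a pool, so these shares need not hold for the arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.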

Results

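Transcript levels of 20938 genes were compared between root tips of the smb brn1 brn2 triple mutant and wild type, and between root tips with dexamethasone-induced SMB overexpression and control root tips. SMB (SOMBRERO), BRN1 and BRN2 (BEARSKIN1 and BEARSKIN2) are related NAC transcription factors of the root cap. Each comparison had 2 dye-swapped arrays of independently isolated RNA pools, and values below are mean log2 ratios ± SD of the 2 arrays (n = 2), with limma's adjusted p. Across genes, which are not independent replicates, the log2 ratios of the mutant arrays correlated at r = 0.68 (Spearman 0.37) and those of the overexpression arrays at r = 0.56 (Spearman 0.28). Arrays of different comparisons correlated at Spearman -0.14 to 0.30 (Pearson -0.30 to 0.11): the second mutant and second overexpression arrays, at Spearman 0.30, agreed in rank as much as the overexpression replicates did.

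The targeted genes were measured by 1 probe each. In the triple mutant BRN2 (AT4G10350) was not well above background and at least 13.6-fold lower than in wild type (adjusted p = 0.000331). BRN1 (AT1G33280) fell by 3.59 on the log2 scale (SD 0.24, adjusted p = 0.000118), with 1 of the 2 mutant pools not well above background. With the processed signals it stood at -6.60. SMB (AT1G79580) stood at -0.57 ± 0.23 in the mutant and was not called (adjusted p = 0.0808). With each comparison fitted alone it was called at the same ratio (adjusted p = 0.0271; 0.000418 to 0.782 over the alternatives). Where its probe lies relative to the mutation is not given in the sources used here, so its level does not check the smb label. On overexpression SMB rose by 4.20 ± 0.12 (18.4-fold, adjusted p = 6.37e-05), BRN2 by 2.83 ± 0.02 (adjusted p = 0.000463) and BRN1 by 1.85 ± 0.19 (adjusted p = 0.000768). The call of BRN1 was lost with the processed signals, at 1.88 (adjusted p = 0.125; 8.22e-32 to 0.125 over the alternatives). RCPG (AT1G65570), a root cap polygalacturonase that degrades pectin, fell by 4.32 in the mutant (SD 0.45, adjusted p = 0.000368). On overexpression it was 2.55-fold higher (1.35 ± 0.47, adjusted p = 0.0155).

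**Figure D1:**
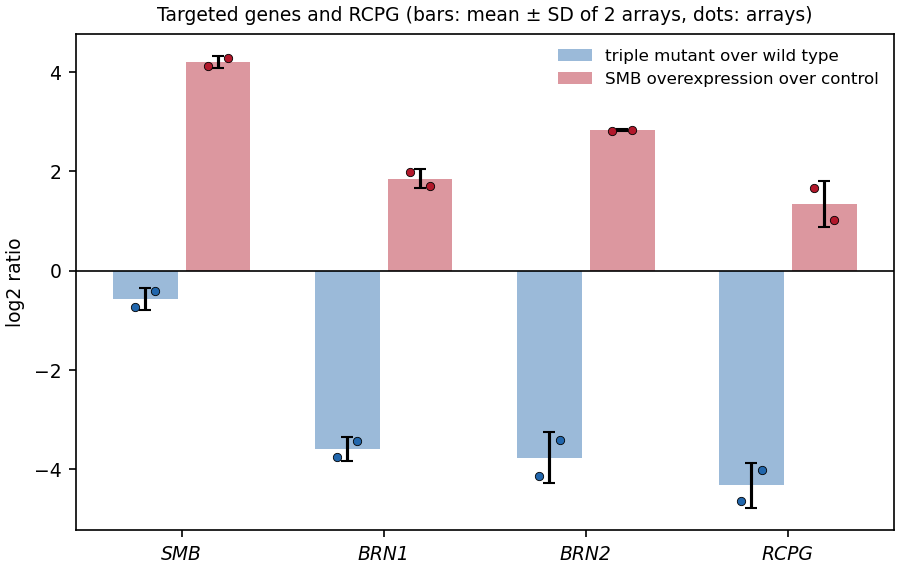
Log2 ratios of SMB, BRN1, BRN2 and RCPG in the triple mutant over wild type (blue) and on SMB overexpression over control (red); bars are means, error bars the SD and dots the 2 arrays of each comparison. All 4 genes lie above 0 on both overexpression arrays and below 0 on both mutant arrays, with SMB in the mutant at -0.57 and not called; the bar of BRN2 in the mutant is a measured ratio against a group not well above background.

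The mutant comparison asks which root tip transcripts depend on the 3 NAC genes together. In the triple mutant 331 genes were higher and 199 lower than in wild type, and all 530 had the same sign on both arrays. The root myrosinase gene BGLU35 (TGG5), which encodes a glucosinolate-cleaving enzyme, fell by 7.22 (SD 0.12, adjusted p = 5.84e-06), a 149-fold change. Its relative BGLU34 (TGG4) fell by 4.29 (SD 0.34, adjusted p = 8.29e-05). AT3G06460, of a fatty acid elongase family, was at -5.53 ± 0.17 (adjusted p = 1.27e-05). The genes AT3G20160 (a putative geranylgeranyl diphosphate synthase) and AT5G58784 (a dehydrodolichyl diphosphate synthase) were not well above background in the mutant and at least 15.4-fold and 14.1-fold lower. The other genes among the 10 lowest were AT3G49190 (-5.06 ± 0.34), MRD1 (-4.98 ± 0.35), RCPG, and the late embryogenesis abundant protein-related AT3G19430 (-4.64 ± 0.12) and AT5G60530 (-4.26 ± 0.39). AT3G06460 and AT3G49190 were well above background in 1 of the 2 mutant pools.

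The 10 genes with the highest ratios in the mutant rose by 2.11 to 3.64 on the log2 scale. The trypsin inhibitor gene TI1 rose most, by 3.64 ± 0.23 (adjusted p = 0.00143), with 1 of the 2 wild-type pools not well above background. With the processed signals it stood at 6.15. It was followed by the desaturase gene ADS4 (3.22 ± 0.27), the SKU5-like gene sks9 (2.99 ± 0.28) and the major latex protein-related AT4G23680 (2.70 ± 0.13). The ribonuclease gene RNS1 (2.58 ± 0.10), the pectinesterase gene ATPMEPCRB (2.26 ± 0.04) and SEN1, a gene of darkness and senescence (2.11 ± 0.46), were among them. So were AT5G44572 (2.64 ± 0.02), AT2G37870 (2.44 ± 0.78) and AT3G22060 (2.14 ± 0.36). Their adjusted p lay between 0.000223 for ADS4 and 0.0085 for AT2G37870.

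Genes of the endodermal barriers moved in opposite directions in the mutant. Among 8 genes of the endodermis and Casparian strip, those that fell included CASP2 (-0.79 ± 0.01), CASP5 (-0.75 ± 0.17), CASP1 (-0.68 ± 0.20) and CASP4 (-0.62 ± 0.06), which encode membrane scaffold proteins of the strip. The list's median was -0.66 (camera adjusted p = 1.54e-09; adjusted p = 0.607 with an estimated correlation). Of 13 suberin and cutin genes, 5 rose (8 adjusted over the list alone): CYP86A1 (1.64 ± 0.00), GPAT5 (1.53 ± 0.06), FAR5 (1.24 ± 0.32), FAR4 (0.96 ± 0.27) and FAR1 (0.58 ± 0.01), all enzymes that make suberin monomers. The list's median was 0.69 (camera adjusted p = 2.53e-05; adjusted p = 0.607 with an estimated correlation). The calls of CASP4, CASP2 and CASP5 were lost in 9, 8 and 8 of 21 alternatives, and those of FAR4, FAR5 and GPAT5 in 7, 6 and 5.

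Wall-loosening genes rose in part. Of 19 expansin and xyloglucan enzyme genes, 3 rose: EXPA8 (1.53 ± 0.32), EXPA1 (1.07 ± 0.07) and EXPA10 (0.68 ± 0.26). Adjusted over the list alone, 7 rose and 2 fell (median 0.27, camera adjusted p = 0.0154). Of 13 columella, starch and gravity genes, IAA33 (1.14 ± 0.03) and LZY4 (0.88 ± 0.22) rose, and 4 did adjusted over the list alone (median 0.11, camera adjusted p = 0.0431). EXPA10 lost its call in 6 of 20 alternatives, with values of 0.50 to 1.94, the highest with the processed signals. LZY4 and IAA33 lost theirs in 7 and 5 of 21. Of 14 defence and jasmonate genes, no member was called by limma over all genes, 9 had an unadjusted p under 0.05, and 7 rose and 2 fell adjusted over the list alone (median 0.35, camera adjusted p = 0.00656). For each of these 3 lists the adjusted p was 0.607 with an estimated correlation. That correlation was -0.02 for the expansin list, 0.05 for the columella list and -0.05 for the defence list. The expansin and defence lists thus lost their calls at a correlation below the preset 0.01. For the Casparian strip and suberin lists it was 0.87 and 0.46. The 9 cell separation enzymes split: RCPG, the endoglucanase gene CEL5 (-1.23 ± 0.38) and PGX1 (-0.73 ± 0.22) fell. The polygalacturonase gene QRT2 (1.34 ± 0.03), the pectin methylesterase gene QRT1 (1.37 ± 0.02) and XTH5 (1.08 ± 0.11) rose. As a list they were not called (camera adjusted p = 0.711; called with median centring at 0.0389 and a median of -0.01), and adjusted over the list alone 3 rose and 4 fell.

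The other lists were not called in the mutant and held no gene called by limma. Their medians (camera adjusted p; members with an unadjusted p under 0.05) were -0.06 for programmed cell death (0.504; 4 of 10), -0.06 for other NAC regulators (0.748; 1 of 16), -0.11 for the secondary cell wall (0.0983; 2 of 24), -0.09 for lignin (0.141; 4 of 17), 0.05 for root hairs (0.376; 3 of 17) and 0.12 for epidermal patterning (0.352; 2 of 9). They were -0.17 for the stem cell niche and meristem (0.268; 5 of 17), 0.03 for the mitotic cycle (0.647; 0 of 21), 0.07 for DNA replication (0.319; 1 of 13) and -0.07 for phloem (0.311; 0 of 11). They were -0.04 for photosynthesis (0.627; 0 of 22), 0.02 for auxin response (0.701; 4 of 17) and 0.29 for ER bodies (0.084; 2 of 5). Adjusted over the list alone, 1 programmed cell death gene rose (CEP1) and 2 fell (RNS3 and EXI1), and 2 lignin genes fell (PRX72 and PRX64). In the same way, 2 root hair genes rose (PRP1 and RSL1) and 1 fell (RSL2), and 1 epidermal patterning gene rose (WER). Median, mean and test differed in sign for cell separation enzymes, other NAC regulators and auxin response.

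The mutant arrays differed from each other in rapid stress and touch response genes, a list written after the data were seen. All 28 of them were below 0 on both mutant arrays, with medians of -1.98 and -1.04. Of them 5 were called lower, namely LOX3 (-2.90), LOX4 (-1.91), JAZ7 (-1.91), JAZ10 (-1.63) and JAZ8 (-1.49). No p is given for the list, since it was written from such genes. These 5 are genes of jasmonate synthesis and response, and their direction was opposite to the call of the defence and jasmonate list. The counts of the mutant comparison rested on both arrays: without replicate 1, 7 genes were higher and 17 lower, without replicate 2, 4 and 21, and without either overexpression array, 669 and 837. With median centring in place of loess 41.4% of the calls were higher, against 62.5% with loess. The columella list lost its call in 6 settings besides the other set tests, mutant replicate 2 left out among them, at adjusted p of 0.0507 to 0.0940. The defence list lost it with median centring (median 0.36, camera adjusted p = 0.347).

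The overexpression comparison asks which transcripts change within 17 h when SMB is raised. The control's genotype, and whether it received dexamethasone, are not given in the sources used here. An effect of dexamethasone or of the line therefore cannot be separated from that of SMB. On overexpression 729 genes were higher and 482 lower than in control, and all had the same sign on both arrays except SZF1, which was measured on 1 array. The most raised gene was AT3G54450, a transporter gene, which rose by 6.51 ± 0.32 (91.0-fold, adjusted p = 2.9e-05). Next to SMB itself, EDA36 (4.14 ± 0.08), AT3G20160 (4.07 ± 0.14), the MADS-box gene AT1G17310 (3.75 ± 0.07) and the homocysteine methyltransferase gene HMT3 (3.71 ± 0.11) stood highest. Then AT1G51030 (3.67 ± 0.39), AT2G37700 (3.6 ± 0.58), AT3G06460 (3.55 ± 0.03) and the ribonuclease gene RNS3 (3.49 ± 0.46) made up the 10 highest. The 10 lowest were led by AT3G20360, which encodes a MATH domain protein (-4.11 ± 0.26, adjusted p = 0.000138), and CER4, an alcohol-forming fatty acyl-CoA reductase of wax synthesis (-3.65 ± 0.07, adjusted p = 6.37e-05). They held the peroxidase genes AT1G14550 (-2.66 ± 0.12) and PER4 (-1.98 ± 0.24), the lipase-like AT2G19050 (-2.22 ± 0.06), the receptor-like kinase gene AT3G46400 (-2.34 ± 0.26) and PCK2 (-2.01 ± 0.17). AT1G49030 (-2.72 ± 0.22), AT5G44585 (-2.69 ± 0.23) and AT3G22250 (-2.14 ± 0.01; 1 of the 2 overexpression pools not well above background) completed them.

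Of 10 genes of developmental programmed cell death, 8 rose on overexpression (9 adjusted over the list alone), with a median of 2.07 (camera adjusted p = 1.66e-12; adjusted p = 0.481 with an estimated correlation). They included RNS3, the metacaspase gene MC9 (3.17 ± 0.64), EXI1 (3.12 ± 0.39) and the aspartic protease gene PASPA3 (2.95 ± 0.06). Of 24 secondary cell wall genes, 17 rose, with a median of 0.86 (camera adjusted p = 2.57e-15; adjusted p = 0.481 with an estimated correlation). Among them were the fasciclin-like FLA11 (1.3 ± 0.01) and FLA12 (1.23 ± 0.26), the xylan synthesis gene IRX9 (1.29 ± 0.26) and the regulator gene MYB103 (0.88 ± 0.05). Adjusted over the list alone, 21 of the 24 rose and GXM3 fell. Of 16 other NAC regulators, 5 rose (6 adjusted over the list alone), namely SND3 (1.24 ± 0.43), SND2 (0.90 ± 0.22), ANAC087 (0.88 ± 0.39), the vessel regulator VND7 (0.84 ± 0.24) and XND1 (0.63 ± 0.08). The median of the list was 0.26 (camera adjusted p = 0.00779; adjusted p = 0.603 with an estimated correlation), and the calls of ANAC087 and VND7 were lost in 9 of 21 alternatives each and that of XND1 in 7. Of 9 cell separation enzymes, RCPG and XTH5 (1.94 ± 0.07) rose. In this list 4 rose and PGX1 fell adjusted over the list alone (median 0.24, camera adjusted p = 0.0177; adjusted p = 0.603 with an estimated correlation).

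Genes of the root epidermis fell. Of 17 root hair genes 8 fell (10 adjusted over the list alone) and all 17 lay below 0, with a median of -0.49 (camera adjusted p = 3.95e-10; adjusted p = 0.481 with an estimated correlation). They included RSL4 (-1.08 ± 0.22), which promotes hair growth, RBOHC (-0.95 ± 0.39), an NADPH oxidase of hair tips, RSL2 (-0.78 ± 0.27) and ADF11 (-0.68 ± 0.25). Of 9 epidermal patterning genes, 3 fell (5 adjusted over the list alone): MYB23 (-1.04 ± 0.21), CPC (-0.58 ± 0.13) and GL2 (-0.55 ± 0.16). The median was -0.42 (camera adjusted p = 0.000107; adjusted p = 0.481 with an estimated correlation). Of 21 alternatives GL2 lost its call in 11 (adjusted p up to 0.719), CPC and ADF11 in 10 each, RSL2 in 9 and RBOHC in 8.

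Smaller shifts were called for 6 more lists. Among 17 stem cell niche and meristem genes the formative cyclin gene CYCD6;1 rose (1.29 ± 0.12; 2 rose adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.00779). All 21 mitotic genes lay above 0 (median 0.22, camera adjusted p = 0.000912), while no single one was called by limma and 4 had an unadjusted p under 0.05. Among 13 DNA replication genes CYCD3;1 rose (0.71 ± 0.29; 1 adjusted over the list alone; median 0.14, camera adjusted p = 0.0437). Among 11 phloem genes NAC045 rose (0.79 ± 0.04; 2 adjusted over the list alone; median 0.21, camera adjusted p = 0.0054). The 22 photosynthesis genes, markers of shoot tissue, had a median of 0.27 (camera adjusted p = 0.00836), with no member called by limma and 4 at an unadjusted p under 0.05. Of 5 ER body genes MEB2 fell (-0.54 ± 0.08; 1 adjusted over the list alone; median -0.20, camera adjusted p = 0.0437). With an estimated correlation the adjusted p of these 6 lists was 0.481 to 0.617. The call of MEB2 was lost in 11 of 21 alternatives, that of CYCD3;1 in 10 and that of NAC045 in 6.

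The remaining 7 lists were not called on overexpression. The median of lignin genes was 0.17 (camera adjusted p = 0.0614), and PRX64 (0.85 ± 0.10) rose among 17. Expansins and xyloglucan enzymes had a median of -0.08 (0.123), with EXPA14 (0.82 ± 0.29) and XTH4 (0.58 ± 0.14) higher and XTH17 (-1.75 ± 0.06) and EXPA8 (-0.69 ± 0.04) lower. The columella list had a median of 0.13 (0.0614), with IAA33 (0.90 ± 0.37) and the starch synthesis gene ADG1 (0.58 ± 0.21) higher. Auxin response had one of 0.08 (0.811), with GH3.1 (1.47 ± 0.48), IAA1 (1.16 ± 0.12) and IAA29 (0.59 ± 0.05) higher. Casparian strip genes had a median of -0.13 (0.0597) with CASP4 (-0.54 ± 0.07) lower. Suberin and cutin genes had one of 0.17 (0.142) with KCS20 (-0.59 ± 0.04) lower, and defence genes one of 0.09 (0.438) with ORA59 (0.70 ± 0.17) higher and FRK1 (-1.29 ± 0.02) lower. Adjusted over the list alone, 1 lignin gene, 2 columella genes, 3 expansin list genes, 4 auxin genes, 1 suberin gene and 2 defence genes rose. In turn 6 expansin list genes, 4 auxin genes, 1 Casparian strip gene, 1 suberin gene and 1 defence gene fell. Over 21 alternatives CASP4 and EXPA8 lost their calls in 12 each, KCS20 and XTH4 in 11 each, ADG1 in 10, IAA29 in 9, EXPA14 and IAA33 in 8 each, ORA59 in 7 and IAA1 in 5. With 1 array left out, 4 of the 7 lists were called: suberin (median 0.40, adjusted p = 0.00392) and lignin (0.28, 0.00392) higher without overexpression replicate 2, and Casparian strip genes lower (-0.26, 0.0138) and the columella list higher (0.11, 0.0492) without overexpression replicate 1. Without a filter the lignin, Casparian strip and columella lists were called (adjusted p = 0.0405, 0.0424 and 0.0433), and with a filter on all 8 channels the lignin list was (0.0493). CASP1, FAR1, QRT1, PGX1, SND2 and the genes named for a count adjusted over the list alone were named after their values had been seen.

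The median of the rapid stress and touch response genes was 1.61 on the first and -0.66 on the second overexpression array. Opposite signs on these arrays were found for 25 of the 28, and for 43.2% of all genes. The counts were 398 higher and 330 lower without overexpression replicate 1, 1366 and 461 without replicate 2, and 420 and 190 without either mutant array. With median centring 72.4% of the calls were higher, against 60.2% with loess. The meristem, mitotic, DNA replication, photosynthesis and ER body lists then lost their calls, at adjusted p of 0.0563 to 0.221. Their medians with median centring were 0.22, 0.25, 0.17, 0.29 and -0.16. Without overexpression replicate 1 the cell separation, phloem and photosynthesis lists lost their calls, with medians of 0.08, 0.14 and 0.05. Without replicate 2 the meristem, mitotic, DNA replication and ER body lists lost theirs, with medians of 0.16, 0.15, 0.06 and -0.14. The cell separation list also lost it with a trended robust prior (0.0861), and the DNA replication and ER body lists with offset 0, the processed signals and the deposited value table. The DNA replication list lost it with the mean of all probes too (0.0573).

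**Figure D2:**
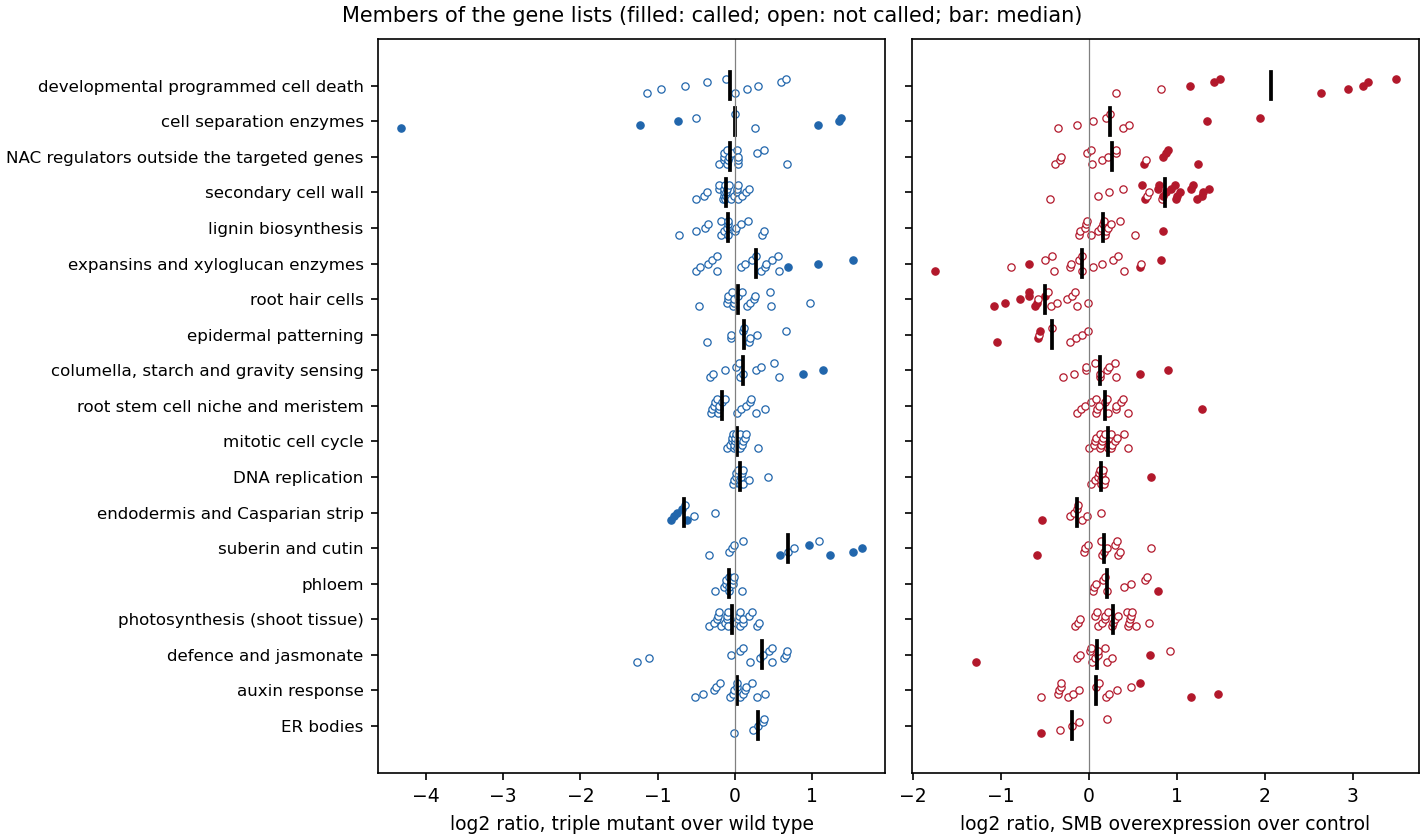
Log2 ratios of the members of the 19 gene lists in the triple mutant over wild type (left) and on SMB overexpression over control (right); filled points are called genes, open points are not called and bars are list medians. The programmed cell death list has its median at 2.07 on overexpression and at -0.06 in the mutant, and the suberin list at 0.17 and 0.69.

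The design implies asking whether genes lower in the mutant are those higher on SMB overexpression. Among genes lower in the mutant 57 were higher on overexpression, where independent lists would share 6.93 (Fisher's exact test, odds ratio 12, 95% interval 8.57 to 16.6, adjusted p = 1.29e-35 over 4 tests). In all 4 tests genes count as independent units, which genes that move together are not, so interval and p describe no replication over pools. The 57 include BRN1 and BRN2, which are themselves mutated in the triple mutant. Besides BRN2, the genes with the largest opposite changes, all called in both, were BGLU35 (3.29 ± 0.17 on overexpression), AT3G06460, AT3G49190 (3.34 ± 0.31), AT5G58784 (3.20 ± 0.10) and AT3G20160. The myrosinase-binding protein-like MLP-300B (-3.47 ± 0.02 and 3.13 ± 0.24), BGLU34 (2.76 ± 0.11), AT5G54370 (-2.57 ± 0.37 and 2.53 ± 0.25) and the desaturase family gene AT1G06090 (-2.52 ± 0.36 and 3.23 ± 0.31) followed. The 199 genes lower in the mutant had a median of 0.02 on overexpression, and 104 of them (52.3%) lay above 0, against 54.1% of all genes. Of the 331 genes higher in the mutant 229 (69.2%) lay above 0 there too, with a median of 0.14, which is the same and not the opposite direction. Of the 96 genes lower in the mutant by at least 1 on the log2 scale, 44 were called higher and 9 lower on overexpression, with a median of 0.63. Among genes higher in the mutant 15 were lower on overexpression, against 7.62 for independent lists (odds ratio 2.05, adjusted p = 0.0140).

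Genes also moved the same way in both comparisons: 50 were higher in both (11.5 for independent lists, odds ratio 5.22, adjusted p = 2.17e-18) and 37 lower in both (4.58, odds ratio 10.4, adjusted p = 9.70e-23). RNS1 was raised in both, by 2.58 ± 0.10 in the mutant and 2.18 ± 0.15 on overexpression. The transcription factor gene AT5G01380 (1.74 ± 0.10 and 1.62 ± 0.47), the nucellin-like AT1G44130 (1.77 ± 0.61 and 1.69 ± 0.47), AT5G60520 (1.61 ± 0.28 and 1.25 ± 0.13), AT5G45630 (1.51 ± 0.43 and 1.72 ± 0.52) and the sulfate transporter gene SULTR2;1 (1.45 ± 0.15 and 1.32 ± 0.85) rose in both, the last with its calls lost in 8 and 10 of 21 alternatives. AT5G45630 lost its mutant call in 5 of 20 and ranged from 1.2 to 3.32 in the mutant and 1.35 to 4.01 on overexpression. AT1G44130 ranged from 1.34 to 3.49 and 1.35 to 2.52, with 2 of 20 lost in each. So did CYP709B2 (1.41 ± 0.42 and 1.36 ± 0.07), AT5G18220 (1.41 ± 0.28 and 1.32 ± 0.00) and sks15 (1.24 ± 0.17 and 2.37 ± 0.22). The kinase gene CIPK13 fell in both (-1.28 ± 0.56 and -1.40 ± 0.04), with its mutant call lost in 5 of 21. Across all 20938 genes, which are not independent replicates, the log2 ratios of the comparisons correlated at Pearson r = -0.08 and Spearman rho = 0.09. The 72 opposite genes became 16 and 19 without mutant replicate 1 and 2 and 336 without overexpression replicate 2. The 87 genes of the same sign became 2, 1, 150 and 178 without mutant replicate 1, mutant replicate 2, overexpression replicate 1 and overexpression replicate 2.

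**Figure D3:**
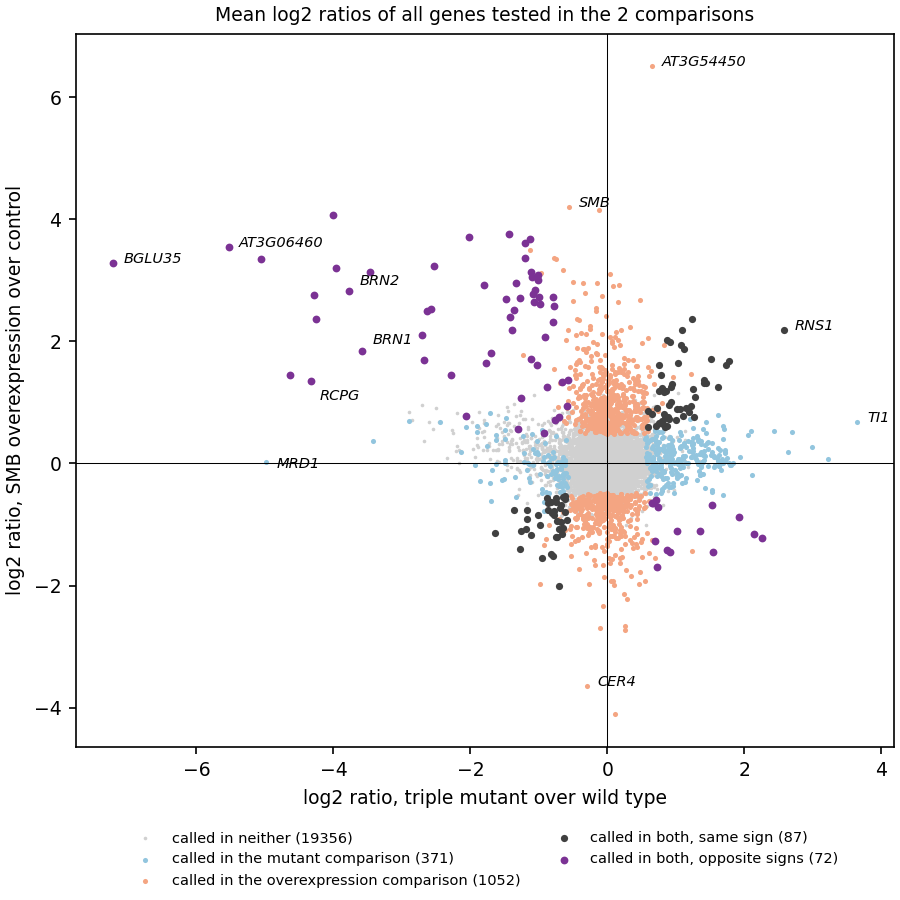
Mean log2 ratio of each of 20938 genes in the triple mutant over wild type (horizontal) and on SMB overexpression over control (vertical); colours mark genes called in neither, either or both comparisons. The 72 genes called with opposite signs include BGLU35 at -7.22 and 3.29, and 87 were called with the same sign, RNS1 among them at 2.58 and 2.18.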

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

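The probes without a locus in the reference table were tested after the other results had been seen. These 3223 probes past the filter on background enter no comparison above, and a signal in them was looked for because no result draws on them. In the triple mutant limma called 15 of them higher and 16 lower than in wild type, with log2 ratios from -4.26 to 2.30. On SMB overexpression 40 were higher and 43 lower than in control, from -1.95 to 3.41. The shares called, 0.962% and 2.58%, lay below those of the named genes in the same fit, 2.34% and 5.59%. Their genes were not identified here and no explanation was tested.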

How the results depend on the processing

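The crossed pairing, the run on all probes without regard to a locus and families without rapid stress and touch response genes were chosen after the data had been seen. A limit is that each comparison rests on 2 arrays and that each RNA pool was measured once, so genes with a change near 1 on the log2 scale were recovered in about as many cases as they were missed in simulated data, and genes not well above background in a group have only a bound there. No spot was saturated, so leaving out saturated probes removed nothing. Lists were not run with separate channels or with a minimum log2 ratio, which have no set test. The targeted genes BRN1 and BRN2 in the mutant and SMB and BRN2 on overexpression kept their direction and call in all alternatives run. BRN1 and BRN2 were not tested with the filter on all 8 channels. Of 218 results for named genes, 122 of them called, none of the alternatives reversed the direction of a called one. Background correction left out ended no call. Between-array normalisation evens out brightness and leaves the ratios unchanged apart from the choice of probe, so that it ended no call says little. The processed signals and the deposited value table, which hold nearly the same ratios, ended 35 each, normexp with offset 0 ended 19 and median centring ended 25. Leaving out mutant replicate 1 or 2 ended most, 52 and 51, overexpression replicate 1 or 2 ended 21 and 5, the replicate block 35, a log2 ratio of at least 1 ended 29 and each comparison fitted alone 20. The other alternatives ended at most 5 each. The log2 ratio grew by more than 1.5 times for 15 of the 122 with the processed signals and 4 with offset 0 (EXPA10 and AT5G58784 in the mutant and AT5G45630 in both). It shrank as much for 4 with the mean of all probes (AT2G37870, AT4G23680 and SEN1 in the mutant and PCK2 on overexpression) and for SULTR2;1 without overexpression replicate 1. Where no cause is named below, the cause was not tested.

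The counts of genes higher and lower in the mutant were 331 and 199, those on overexpression 729 and 482, opposite calls 72, calls of the same sign 87, called lists 5 and 12 and called families 5 and 11. With normexp offset 0 the genes lower in the mutant were 125 and the overexpression families 7. With the processed signals these were 97 and 6, the overexpression genes 437 higher and 299 lower, and calls of the same sign 42; with the deposited value table they were 98 and 5, 437 and 300, and 43. BRN1 on overexpression stood at 1.88 and was not called with either (adjusted p = 0.125; 8.22e-32 to 0.125 over the alternatives). With median centring 325 genes were lower in the mutant, 477 higher and 182 lower on overexpression and 38 of the same sign, with 7 lists and 6 families called on overexpression. A filter on all 8 channels left 132 genes lower in the mutant; of the 530 genes called there, 446 were still tested with the same sign and 379 called. With each comparison fitted alone the counts were 669 and 837 in the mutant and 420 and 190 on overexpression. A log2 ratio of at least 1 left 162 and 96 in the mutant, 318 and 138 on overexpression, 47 opposite and 20 of the same sign, by its construction. SMB in the mutant, at -0.57, was called with each comparison fitted alone (adjusted p = 0.0271) and with separate channels (0.0385), over a range of 0.000418 to 0.782. Leaving out either overexpression array gave the same mutant fit as fitting that comparison alone. These settings are therefore not separate evidence where alternatives are counted. Camera with an estimated correlation and fry called 0 and 0 lists, against 5 and 12.

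Leaving out 1 array at a time left a comparison with a lone array, which was assumed to vary like the other comparison. Genes higher in the mutant then ranged from 4 to 669 and lower ones from 17 to 837, genes higher on overexpression from 398 to 1366 and lower ones from 190 to 461, opposite calls from 16 to 336 and calls of the same sign from 1 to 178. Lists called in the mutant ranged from 5 to 12 and families from 5 to 14. SMB in the mutant ranged from -0.73 to -0.40. The photosynthesis list in the mutant, not called with both arrays at a median of -0.04, was called in the other direction without mutant replicate 1, at a median of 0.29 (adjusted p = 0.00894). Without mutant replicate 2 its median was -0.28, called lower (adjusted p = 0.000548). With mutant replicate 2 left out, secondary wall, lignin, phloem and programmed cell death lists were called lower in the mutant (medians -0.36, -0.23, -0.23 and -0.52). Root hair, mitotic and DNA replication lists were called higher (0.11, 0.15 and 0.19). The ER body list was called in the mutant without mutant replicate 1 (adjusted p = 0.0187) and with the mean of all probes (0.0433).

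The replicate numbers did not pair the samples: deviations of same-numbered arrays of the comparisons correlated at r = -0.33 across genes (Spearman -0.16), and the numbers also stand for the dye orientation. With the replicate block 130 genes were higher and 67 lower in the mutant, 371 and 201 on overexpression, 41 opposite and 25 of the same sign, in a fit with fewer residual degrees of freedom. A crossed pairing as a block called 1057 and 1346 genes in the mutant, 1915 and 1141 on overexpression, 418 opposite and 480 of the same sign, with SMB at -0.57 in the mutant called. It left 4 lists called in the mutant and 8 on overexpression: the defence list in the mutant (adjusted p = 0.205) and the meristem (0.0625), mitotic (0.0625), DNA replication (0.189) and ER body lists (0.170) on overexpression lost their calls.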

Other observations

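The tests weighed for the 3 patterns in the last paragraphs, the neighbouring genes, the rapid stress and touch response list and the families without its members were chosen after the results had been seen; the tests of the whole gene families were planned.

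Gene families were formed by keywords in the descriptions, and some, such as expansins and cyclins, share genes with the lists. In the triple mutant 13 of 163 cytochrome P450 genes rose, led by CYP86A1 (1.64), CYP86A4 (1.61), CYP709B2 (1.41) and CYP86A2 (1.41), and CYP702A2 and CYP96A14P fell (family median 0.12, camera adjusted p = 0.00130). Of 49 GDSL lipase-like genes 7 rose, AT5G37690 (1.78) and AT2G23540 (1.69) most, and AT2G30220 fell (median 0.13, adjusted p = 0.00130). Of 24 expansin genes EXPA12 (1.54) rose besides EXPA8, EXPA1 and EXPA10 (median 0.11, adjusted p = 0.0200). Ethylene response factor genes had a median of -0.28 over 29 genes with TDR1 called lower (adjusted p = 0.00172). They include 4 of the rapid stress and touch response genes, ERF5, ERF6, ERF13 and ERF104, for which pool and genotype were not separated. Without these the median was -0.12 (adjusted p = 0.0309). The 31 aquaporin genes had a median of -0.20 with no member called by limma and 15 at an unadjusted p under 0.05 (adjusted p = 0.00130). With an estimated correlation the adjusted p of these 5 families was 0.932. The medians of these 5 kept their sign in all 18 alternatives run on families. The calls of the ethylene response factor and GDSL families were kept in all 18, those of the other 3 in 17 each.

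On SMB overexpression 13 of 70 genes matched as pectinesterases rose and 6 fell, from AT3G47400 (3.34) to AT2G47550 (-1.47) (median 0.08, camera adjusted p = 0.0220). The match also takes in inhibitors and other relatives of these enzymes, such as the inhibitor C/VIF2 and the SKU5-like sks16 among those that rose. Enzymes and inhibitors were not counted apart, so the genes that rose are not a count of enzymes. Of 163 cytochrome P450 genes 14 rose, CYP96A14P (3.08) and CYP96A8 (1.94) most, and CYP81D11 (-1.46) fell (median 0.12, adjusted p = 0.0102). The laccase genes LAC4 (0.99), LAC10 (0.93), LAC12 (0.72) and LAC6 (0.52) rose among 16 (median 0.27, adjusted p = 0.0193). Of 57 auxin-responsive and SAUR genes 8 rose and AT5G42410 fell (median 0.14, adjusted p = 0.0220). Among 32 genes matched as cysteine proteases XCP2 (1.15), CP1 (0.73) and CYS2 (1.40), the last an inhibitor, rose and AT3G19390 (-0.57) fell (median 0.15, adjusted p = 0.0193). Among 74 matched as cyclins CYCD6;1, CYCD3;1 and KRP6 (0.70), the last an inhibitor of cyclin-dependent kinases, rose (median 0.10, adjusted p = 0.0326). Of 109 glycosyl hydrolase genes 9 rose and GH9C1, KOR2, GH9B13 and AT4G01890 fell (median 0.07, adjusted p = 0.0479). Ribosomal protein genes (median -0.06 of 322, adjusted p = 0.0102), extensin and proline-rich genes (-0.08 of 99, 0.0479), peroxidase genes (-0.02 of 84, 0.0479) and WRKY genes (-0.02 of 63, 0.0479) were called lower. The medians of these 4 changed sign in at least 1 alternative, with highest values of 0.04, 0.06, 0.01 and 0.15. Calls were kept in 7 of 18 alternatives for peroxidase genes, 8 for glycosyl hydrolase (adjusted p up to 0.315), 9 for WRKY, 11 for extensin and proline-rich and 13 for cyclin genes. They were kept in 16 for pectinesterase, auxin-responsive and cysteine protease genes, and in 17 for laccase, cytochrome P450 and ribosomal protein genes. With an estimated correlation the adjusted p of the 11 families called here was 0.832. The genes named for families were named after their values had been seen.

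The 3 genes on each side of MRD1 and of BRN1 and BRN2 in the mutant, and of AT3G54450 and SMB on overexpression, were tested, 6 per gene, and limma called 0 of them in those comparisons. The log2 ratios of the neighbours ranged from 0.01 to 0.33 for MRD1, from -0.33 to 0.19 for BRN1, from -0.14 to 0.54 for BRN2, from -0.39 to 0.30 for AT3G54450 and from -0.05 to 0.17 for SMB.

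The arrays of the mutant comparison differed from each other for rapid stress and touch response genes, 15 of which were among the 200 genes with the largest difference between these arrays. A gene-specific dye bias as the whole cause would give those 200 genes a difference of the same sign and size in the overexpression arrays, which swap the dyes the same way. The deviation of array 1 from the mean of both arrays had a median size of 0.57 in the mutant comparison. Signed as there, it had a median of -0.65 in the overexpression comparison (quartiles -1.05 and -0.25), and 180 of the 200 genes had the opposite sign. This argues against dye bias as the whole cause; no p is given, since these genes move together. Dim probes are argued against by a median brightness percentile of 60.0 (quartiles 33.9 and 80.7). The state of the plants or pools at harvest may account for it. The control pools, which share a group name, differed by a median of 1.69 over the log2 differences of the 28 genes, pool 2 above pool 1. The median levels of these genes in pools 1 and 2 were 9.59 and 10.75 for the mutant, 12.27 and 12.03 for wild type, 9.37 and 11.22 for control and 10.94 and 10.32 for overexpression, so the wild-type pools differed least. Pools 1 and 2 of each RNA group carried different dyes and lay on different arrays. These levels therefore do not separate pool from dye and array. Because that list was written after such genes had been seen, the test cannot decide, and genotype and pool cannot be told apart for the 5 of these genes called lower in the mutant.

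Genes called in both comparisons with the same sign were 5.40 times as many as independent lists would share. Those called with opposite signs were 4.95 times as many, so the excess is not particular to the same sign. The spread estimate that the comparisons share may raise such counts, but with each comparison fitted alone the ratios were 4.28 for the same sign and 3.85 for opposite signs. Loess normalisation as the whole cause is argued against in the same way, as with median centring in its place they were 4.71 and 6.81. The processed signals, which are dye-normalised within each array, gave 6.34 and 10.2. The genes of the same sign nevertheless fell from 87 to 38 with median centring and to 42 with the processed signals. Those of opposite signs fell from 72 to 64 and 57. The number of genes of the same sign, and whether they outnumber the opposite ones, thus depended on the processing. What remains open for the excess in either direction includes the genotypes themselves, and conditions that both comparisons may have had in common, neither of which was tested.

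Casparian strip genes were lower and suberin genes higher in the triple mutant. Loess as the cause is argued against, since both lists kept their call and direction with median centring in its place. They also kept them with the processed signals, which are themselves dye-normalised within each array, so 4 of 4 list calls were kept. Neither list was called with an estimated correlation (adjusted p = 0.607 each) or with fry (0.121 and 0.193). More older tissue in the mutant root tips may move both lists, and would lower genes of dividing cells. The mitotic list had a median of 0.03 (0.0252; quartiles -0.01 and 0.07) in the mutant, but a small shift of the harvested zone could move it too little to be seen, so older tissue and genotype cannot be told apart for these lists. An effect of the genotype on the endodermis was not tested.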
